A study of Mus musculus with 25 samples.

How the data were processed

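Total lung RNA (6 µg per the labels) from 25 female C57BL/6J mice in 8 groups was hybridised to Affymetrix mouse arrays after biotin labelling by the manufacturer's protocol. The deposited values are signal intensities on a linear scale, 1 per probe set and array, and the labels name GCOS, the Affymetrix operating software, without a version. No summary method, background correction or scaling target is stated, so alternatives to these steps could not be tried. The values ran from 0.53 to 19112, the array medians from 118.05 to 129.28, and 627 to 783 probe sets per array were exactly 1. The number of arrays limits the precision.

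The table held 45101 probe sets, of which 64 Affymetrix control probe sets were left out of the tests. An annotation gave a single gene symbol to 34945 probe sets, several symbols to 932 and none to 9211; the last 2 kinds were left out. Values became log2(signal + 16). Each of 18193 genes was represented by its probe set with the highest mean over all 25 arrays, and genes whose representative had a mean at or below the 40th percentile of all probe sets (6.49 log2 units) were left out, which left 12937 genes. No further normalization was applied, since the largest median log2 fold change of a comparison was 0.0516 in size, and quantile normalization moved a median by at most 0.0497.

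Samples were grouped by treatment as the labels give it: control, 3 compounds, radiation, and radiation with each compound. The labels give no batch and no pairing, and residual correlations between arrays of the same replicate number ran from -0.836 to 0.781, with 7 of 25 arrays correlating best with an array of their own number. All 3 same-number pairs had a correlation over 0.1 in 5 of the comparisons: radiation, and fTyS, against control, radiation+fTyS against fTyS and against radiation, and FTY against SEW. A fit with the number as a block was run beside the fit without it. One limma fit (limma 3.58.1 in R 4.3.3; lmFit with 8 group means, 17 residual degrees of freedom, eBayes with trend) gave 19 comparisons: radiation or a compound against control, radiation with a compound against radiation and against the compound, the compounds against each other with and without radiation, and the interaction of radiation with each compound. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison, and genes with an adjusted p of at most 0.05 were called. SEs of genes are those of the limma fit. For 37 gene lists of cell types, tissues, stress and lipid pathways (685 entries, 630 of them matched to a gene on the array), the shift of a list was tested with camera of limma at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation; of 192 calls at the preset value, 4 held with an estimated correlation. Members were counted as called over all genes and adjusted over the list alone. The SE of a list mean comes from the spread of per-array means in the 8 groups. A list's mean, median and test agreed in sign unless stated, and no called list changed sign with quantile normalization or median centring.

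The radiation score per array was compared between groups with exact two-sided permutation tests. Its genes were chosen on the radiation and control arrays, so 2 other versions were computed, with the 50 genes of smallest p in each direction and with genes chosen on the comparisons of the other compounds (cross-fitted). The slope of the radiation response was taken through the origin across the genes called with radiation, without a p, and its SE by jackknife over arrays. Comparisons that share a reference group were set against 50 simulations without effects. In 10 simulations with 200 changed genes the pipeline recovered 93.4% of 2-fold changes for radiation against control and 92.5% for radiation+fTyS against radiation. False calls were 5.42% and 4.91%. A list shift of 0.5 was called in 4 and 6 of the 10. These rates may not hold for the real arrays, whose genes vary together.

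The named genes are the 10 with the largest increase and the 10 with the largest decrease among called genes whose groups do not overlap in any array, for radiation against control and radiation with a compound against radiation. Elsewhere they are 5 and 5, or the genes with the smallest p where none was called. The non-overlap was not asked of interactions. Up to 4 members of each called list and 14 genes of S1P handling and the DNA-damage response were named as well. Groups, comparisons, lists, this rule and most alternatives were fixed before the data were examined. These alternatives were quantile normalization, median centring, a pseudocount of 1 or 64, no filter or a filter at the 60th percentile, the mean of all probe sets of a gene, eBayes without trend, array weights, the Gapdh 3 prime to 5 prime ratio as a covariate, the replicate number as a block, a fit of only the arrays compared, and leaving out each array. Chosen after the data were seen were the mean of the skeletal muscle list as a covariate, the means of the skeletal muscle and adipocyte lists as covariates, both again without the array labelled control replicate 4, and leaving out each array for the list tests and the radiation scores. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and, for figures, matplotlib 3.10.9.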

Results

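Lung RNA of mice aged 14 to 17 weeks and weighing 20 to 25 g per the labels was measured on 25 Affymetrix arrays. The control group received phosphate-buffered saline (n = 4). Mice of the fTyS, SEW and FTY groups received 0.1 mg/kg of a compound that acts on receptors for sphingosine 1-phosphate (S1P), by intraperitoneal injection 2 times a week (n = 3 each). The radiation group received 25 Gy (n = 3), and the radiation+fTyS, radiation+SEW and radiation+FTY groups received 25 Gy and a compound (n = 3 each). FTY is FTY720 (fingolimod), which is phosphorylated in the body and then binds S1P receptors. fTyS is (S)-FTY720-phosphonate, in which a phosphonate that cannot be hydrolysed like a phosphate ester takes the place of the phosphate of phosphorylated FTY720. SEW is SEW-2871, an agonist selective for S1pr1 that is not built like sphingosine. The time between irradiation and collection is not given. The median half-width of the 95% confidence interval of a log2 fold change was 0.208 against control and 0.222 between groups of 3. Genes tested numbered 12937. Log2 fold changes are given ± SE from limma, means of gene lists ± SE between arrays, and group levels ± SD. Outside the interactions, groups of genes named for their change did not overlap in any array.

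Radiation alone was compared with control to find the genes that the exposure changed. Genes of neutrophils rose: Csf3r, the receptor for granulocyte colony-stimulating factor, by 3.29 ± 0.46, and S100a9 and S100a8, the subunits of calprotectin, by 3.09 ± 0.51 and 2.41 ± 0.44. The mean over 10 neutrophil genes was 7.83 ± 0.34 in control (n = 4) and 9.84 ± 0.40 after radiation (n = 3). This shift of 2.01 ± 0.28 had an adjusted p = 3.29e-13, and adjusted p = 0.0234 with an estimated correlation. Of the 10, 7 rose over all genes and 8 adjusted over the list alone. Genes of monocytes and interstitial macrophages shifted by 0.51 ± 0.10 (adjusted p = 4.61e-08; adjusted p = 0.173 with an estimated correlation). Of these 16 genes, 7 rose over all genes and 9 adjusted over the list alone, among them Cd68 (1.28), Itgam (1.15) and Ccr2 (1.03). Of 29 cytokine, chemokine and adhesion genes 4 rose, over all genes and adjusted over the list alone: Il1b (2.36 ± 0.33), Ccl9 (1.42), Il1rn (1.03) and Ccl6 (0.93). Their list shifted by 0.45 ± 0.11 (adjusted p = 0.000281; adjusted p = 0.176 with an estimated correlation). Targets of the DNA-damage factor p53 shifted by 0.32 ± 0.09 (adjusted p = 0.000161; adjusted p = 0.367 with an estimated correlation). Of 25 targets 5 rose, among them Eda2r (1.38 ± 0.35), Phlda3 (0.93) and Aen (0.84 ± 0.15). Adjusted over the list alone, 13 were higher and 1 lower. On the array labelled control replicate 4 this list averaged 10.15, against 9.56 to 9.71 on the other 12 arrays labelled unirradiated and 10.04 to 10.17 on the 12 irradiated arrays. The inhibitor of the cell cycle Cdkn1a had a fold change of 1.25 ± 0.36 (adjusted p = 0.0538), with an SD of 1.14 in control.

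The other genes with the largest increases were Stfa2l1, a stefin A-like gene (3.80 ± 0.46), Slfn4 (3.05 ± 0.43), the C-type lectin receptors of myeloid cells Clec4d (2.69 ± 0.33) and Clec4e (2.65 ± 0.36), Wfdc17 (2.54 ± 0.29) and Avil (2.10 ± 0.42). The largest decreases were those of Aplnr, the apelin receptor of endothelial cells (-1.77 ± 0.30), Krt79 (-1.51 ± 0.25), the fatty acid binding protein gene Fabp1 (-1.25) and Klra8, a receptor of natural killer cells (-1.11). Next came Gprin3 (-1.10 ± 0.15), Gm33248 (-1.05), Zbed6 (-1.03 ± 0.12), Cdh16 (-0.89), A330076H08Rik (-0.88) and Sox11 (-0.88). Alveolar macrophage genes went both ways, with Ctsk (0.85), Chil3 (0.62) and Ctsd (0.38) higher and Krt79 lower (mean 0.22 ± 0.09; adjusted p = 0.00449; adjusted p = 0.367 with an estimated correlation). Radiation changed 569 genes, 296 higher and 273 lower, 74 of them by over 2-fold. The groups did not overlap for 13.8% of all genes (chance 5.71%). The split depended on the scaling, with 376 higher and 192 lower under quantile normalization and 402 higher and 134 lower under median centring. The count was 1138 with array weights, 867 with a replicate block and 60 when only the 7 arrays were fitted. It was 275 without control replicate 2, 291 without control replicate 3, 884 without control replicate 4, 232 without radiation replicate 1 and 365 without radiation replicate 2. Avil, Fabp1, Klra8, Cdh16, A330076H08Rik and Sox11 lost their call without some array.

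**Figure D1:**
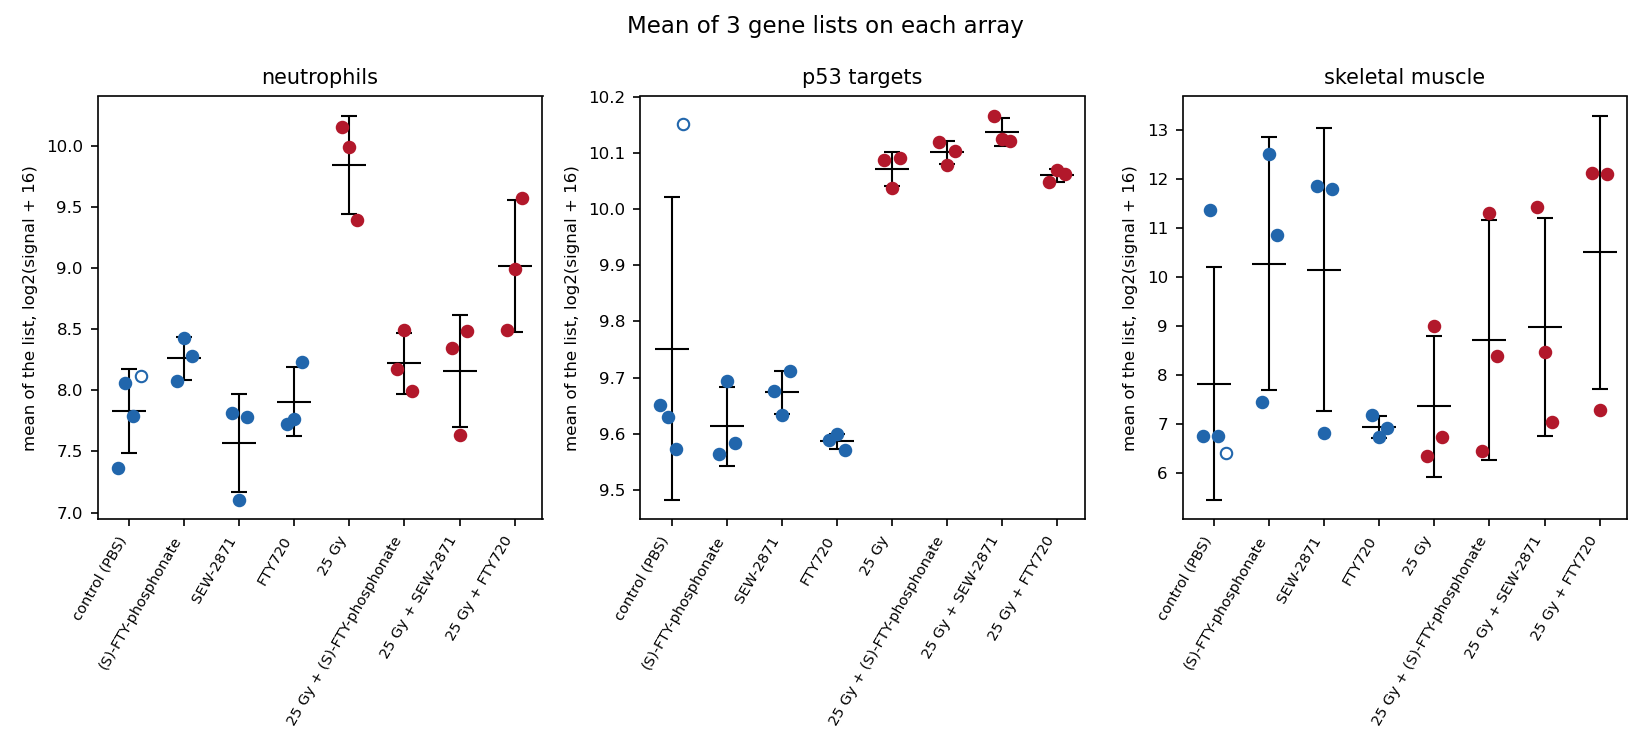
Mean log2 signal of neutrophil genes, p53 target genes and skeletal muscle genes (vertical axes) on each array of the 8 groups (horizontal axis); points are arrays, bars are group means ± SD, blue is unirradiated, red is irradiated, and the open circle is the array labelled control replicate 4. Neutrophil genes stand at 9.39 to 10.15 with radiation alone and at 7.37 to 8.12 in control, p53 targets stand at 10.15 on the open circle, and skeletal muscle genes range from 6.34 to 12.51.

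The 3 compounds were each added to radiation to find what they change in irradiated lung. With fTyS, neutrophil genes fell: the list shifted by -1.62 ± 0.30, from 9.84 ± 0.40 to 8.22 ± 0.25 (n = 3 each). Its adjusted p = 6.25e-12, and adjusted p = 0.0366 with an estimated correlation. Of the 10 genes, 5 fell over all genes and 8 adjusted over the list alone. Csf3r fell by 2.31 ± 0.49, Clec4d by 2.20 ± 0.35, Clec4e by 1.99, the matrix protease Mmp9 by 1.70 ± 0.28, and the activating receptor Trem1 by 1.08. Outside that list, the largest decreases were in Stfa2l1 (-3.15 ± 0.49), the cytokine gene Il1b (-1.76 ± 0.35), Cd300lf (-1.60 ± 0.26), Wfdc17 (-1.57), Sirpb1a (-1.54) and Emilin2 (-1.39). The largest increases were in Angptl1 (0.89 ± 0.19), Clec11a (0.84), the BMP antagonist Chrdl1 (0.80 ± 0.12) and the Wnt enhancer Rspo3 (0.75, but -0.02 by its other probe set). Then came Clec3b (0.72), Klf12 (0.65 ± 0.08), 6820431F20Rik (0.64), Synm (0.63 ± 0.10), the alarmin Il33 (0.63 ± 0.13) and Aass (0.63). B cell genes were higher as a list by 0.96 ± 0.33 (adjusted p = 4.68e-10; adjusted p = 0.393 with an estimated correlation). None of its 15 genes was called over all genes and 12 were adjusted over the list alone, for example Ms4a1 (1.47, adjusted p = 0.13 over all genes). Radiation replicate 1 had a B cell mean of 6.97, against 7.81 for its group. Platelet genes shifted by -0.63 ± 0.21 (adjusted p = 5.38e-05; adjusted p = 0.31 with an estimated correlation). The platelet glycoprotein gene Gp5 fell by 0.48, and 4 of 6 were lower adjusted over the list alone. Cholesterol and fatty acid synthesis genes shifted by 0.29 ± 0.10 (adjusted p = 5.81e-06; adjusted p = 0.31 with an estimated correlation). Of these, 0 of 16 were called over all genes and 4 adjusted over the list alone.

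In all, 111 genes differed between radiation+fTyS and radiation, 54 higher and 57 lower, and 21 of them by over 2-fold. Their groups did not overlap for 17.7% of all genes (chance 10%). Under quantile normalization 27 were higher and 94 lower, and under median centring 18 were higher and 58 lower. The count was 1220 with array weights, 208 with muscle and adipocyte covariates, 254 with these and without control replicate 4, and 0 when only the 6 arrays were fitted. It was 23, 25 and 173 without radiation replicates 1, 2 and 3, and 33, 68 and 18 without radiation+fTyS replicates 1, 2 and 3. Of the 20 genes with the largest changes, 13 lost their call without some array.

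With SEW added to radiation, neutrophil genes were lower by -1.69 ± 0.30, at 8.16 ± 0.46 (n = 3; adjusted p = 1.91e-11; adjusted p = 0.0436 with an estimated correlation). Over all genes 7 of 10 fell, and 8 adjusted over the list alone. Csf3r fell by 3.16 ± 0.49, S100a9 by 2.71 ± 0.55, Clec4d by 2.30 ± 0.35, S100a8 by 2.16, Clec4e by 2.05 and Mmp9 by 1.89. Stfa2l1 (-3.24 ± 0.49), Slfn4 (-2.79 ± 0.46), Il1b (-1.81 ± 0.35) and Cd300lf (-1.79) were the other genes with the largest decreases. Monocyte and interstitial macrophage genes shifted by -0.35 ± 0.11 (adjusted p = 0.000144; adjusted p = 0.402 with an estimated correlation). Itgam (-1.23) and Ccr2 (-1.01) were lower over all genes, and 6 of 16 adjusted over the list alone. The sterol synthesis enzymes Dhcr7 (0.76) and Cyp51 (0.54) rose, as did 5 of 16 genes adjusted over the list alone. Their list of cholesterol and fatty acid synthesis shifted by 0.33 ± 0.10 (adjusted p = 0.000144; adjusted p = 0.402 with an estimated correlation). The largest increases were in Agr2 and Gp2, genes of secretory epithelium (2.32 ± 0.60 and 2.21 ± 0.46), and Calcb (1.81 ± 0.35). They were followed by Fras1 (1.03), Col8a1 (0.98), the urokinase gene Plau (0.95), Gap43 (0.91), Clec11a (0.90), Tmem158 (0.90) and St8sia6 (0.88). The comparison called 321 genes, 178 higher and 143 lower, 44 by over 2-fold. Groups did not overlap for 27.1% of all genes (chance 10%). Quantile normalization gave 106 higher and 182 lower, and median centring 83 higher and 195 lower. The count was 1444 with array weights and 102 with only the 6 arrays fitted. It was 49 and 112 without radiation replicates 1 and 2, and 110, 114 and 82 without radiation+SEW replicates 1, 2 and 3, and 14 of the 20 genes with the largest changes lost their call in this way.

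With FTY added to radiation, neutrophil genes were lower by -0.83 ± 0.30, at 9.02 ± 0.54 (n = 3; adjusted p = 0.000331; adjusted p = 0.492 with an estimated correlation). Clec4d (-1.41) and Trem1 (-0.94 ± 0.22) fell over all genes, and 5 of 10 adjusted over the list alone. Of 16 cholesterol and fatty acid synthesis genes, 5 rose over all genes and 11 adjusted over the list alone, among them Dhcr7 (0.86), Fdft1 (0.66), Insig1 (0.59) and Cyp51 (0.54). The list shifted by 0.42 ± 0.10 (adjusted p = 1.27e-05; adjusted p = 0.492 with an estimated correlation). Immediate early and heat shock genes shifted by -0.52 ± 0.14 (adjusted p = 1.22e-06; adjusted p = 0.492 with an estimated correlation). Jun was lower over all genes (-0.54), and 9 of 19 adjusted over the list alone. The largest increases were in Myl2 (3.88 ± 1.04), Lrrn4 (1.23 ± 0.26), Gsta2 (1.22), Upk3b (1.20 ± 0.22) and Mtfp1 (1.20). Next were the transcription factor Wt1 (1.08 ± 0.25), Nol3 (1.07), Fras1 (1.04), Bnc1 (0.99) and the retinoic acid enzyme Aldh1a2 (0.97 ± 0.18). The largest decreases were in Nr4a3 (-1.50 ± 0.30), the matrix protein gene Thbs1 (-1.36 ± 0.25), Sirpb1a (-1.31), Il1b (-1.30 ± 0.35) and Igsf6 (-1.21). Smaller ones were in Pon1 (-1.0), Trem1, Pirb (-0.93), Tnfrsf12a (-0.87) and Ms4a6c (-0.86, but 0.11 by its other probe set). Acid ceramidase, Asah1, fell by 0.27 ± 0.06, and the p53 regulator Mdm2 by 0.36 ± 0.08. Skeletal muscle genes averaged 10.50 ± 2.79 with radiation+FTY and 7.36 ± 1.44 with radiation, and adipocyte genes 10.62 ± 0.76 and 8.85 ± 0.52.

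Between radiation+FTY and radiation 391 genes differed, 251 higher and 140 lower, 16 by over 2-fold. The groups were apart for 27.7% of all genes (chance 10%). By quantile normalization 210 were higher and 214 lower, and by median centring 139 and 175. The count was 101 with muscle and adipocyte covariates (129 without control replicate 4) and 90 with the muscle covariate (108 without that array). It was 184 with the mean of all probe sets, 1249 with array weights and 6 with only the 6 arrays fitted. It was 93, 187 and 185 without radiation replicates 1, 2 and 3, and 38 and 158 without radiation+FTY replicates 1 and 2. In this way 17 of the 20 genes with the largest changes lost their call, and 14 did with both covariates. All 3 compounds added to radiation changed 23 genes alike. Of these 6 were higher, for example Klf12, Chrdl1 and Pmepa1, and 17 lower, for example Il1b, Clec4d, Stfa2l1, Trem1 and Pirb. No gene was called higher with one compound and lower with another. These comparisons share the radiation arrays, and genes are not independent replicates. The fold changes correlated at 0.655 to 0.807 across genes, against 0.492 to 0.501 in simulations with no effect. Muscle and adipocyte genes varied between the arrays, so this alone shows no common effect.

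**Figure D2:**
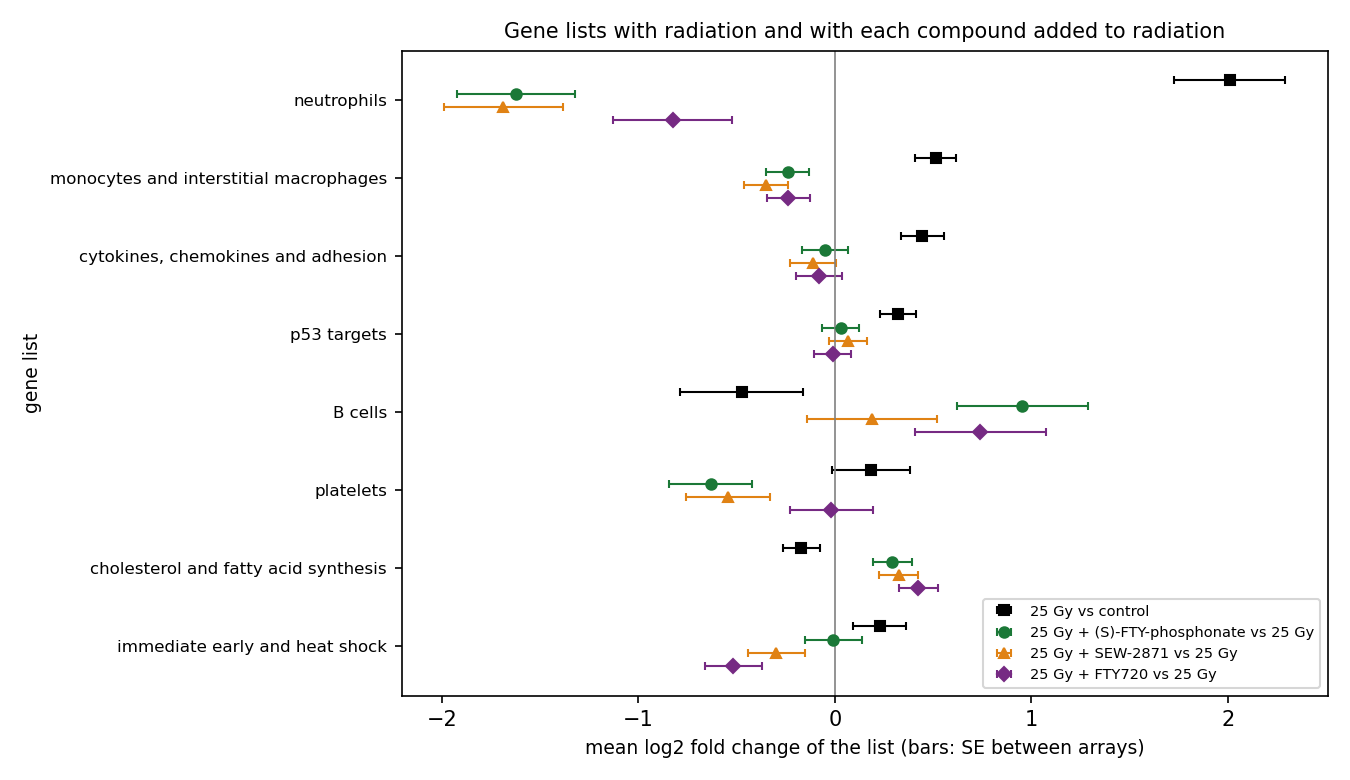
Mean log2 fold change ± SE between arrays (horizontal axis) of 8 gene lists (vertical axis) in radiation against control and in radiation plus each compound against radiation; points are list means. Neutrophil genes stand at 2.01 with radiation against control, and at -1.62, -1.69 and -0.83 with fTyS, SEW and FTY added to radiation.

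A score per array, the mean log2 of the genes higher after radiation less that of the genes lower, was set to 0 in control and reached 1.19 ± 0.259 (SD, n = 3) with radiation. It was 0.465 ± 0.0564 with radiation+fTyS, 0.395 ± 0.0146 with radiation+SEW and 0.695 ± 0.0878 with radiation+FTY, each below radiation alone by more than the spread. The differences were -0.726, -0.796 and -0.496 (exact two-sided permutation p = 0.1 each, the smallest that 20 splits allow). Because the genes were chosen on the radiation and control arrays, these differences are not independent of that choice. With genes chosen on the other 2 compounds, the differences were 0.00886 for fTyS, 0.361 for SEW and -0.0140 for FTY. Without single arrays the fTyS value ran from -0.0182 (without radiation+fTyS replicate 2) to 0.0428 (without radiation+fTyS replicate 1) and the FTY value from -0.102 (without radiation replicate 2) to 0.0877 (without radiation+FTY replicate 3), so that neither has a direction. Radiation alone stood at 0.0471 ± 0.0535 on the version for fTyS, 0.421 ± 0.0613 on that for SEW and 1.04 ± 0.156 on that for FTY (SD, n = 3), with control at 0 ± 0.178, 0.535 and 0.575 (SD, n = 4). The versions for fTyS and SEW did not rise with radiation alone by more than the spread of control. They cannot show a lowered or reversed response. These scores rest on 702 higher and 219 lower genes for fTyS, 24 and 7 for SEW and 29 and 2 for FTY, so that their sizes cannot be compared between compounds. The compounds without radiation lay above control by 0.302 (fTyS, exact p = 0.114), 0.234 (SEW, exact p = 0.171) and 0.236 (FTY, exact p = 0.2), where 35 splits allow 0.0286. Without control replicate 4 these were 0.421, 0.353 and 0.355. With genes chosen on the other compounds they were -0.152, -0.422 and -0.342, and -0.0845, -0.164 and -0.0822 without control replicate 4. Of the other arrays, control replicate 1 (-0.229 for fTyS, -0.544 for FTY), fTyS replicate 3 (-0.0906) and FTY replicate 2 (-0.219) also moved them by over 1.5 times when left out. Radiation with a compound lay above the compound alone by 0.163 (fTyS), 0.161 (SEW) and 0.458 (FTY; exact p = 0.1 each), and by 0.208, 1.20 and 1.37 with genes chosen on the other compounds. Across the 569 radiation genes, which are not independent replicates, the slope of the radiation response under a compound on that without was 0.179 ± 0.0615 for fTyS, 0.246 ± 0.0617 for SEW and 0.502 ± 0.130 for FTY (jackknife SE over arrays). The genes were chosen on the radiation and control arrays, and the slope that this choice alone gives was not tested. Over all genes the slopes were 0.125, 0.0733 and 0.0919, in another order of the compounds.

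Each compound was compared with control in unirradiated lung to find its own effect. Immunoglobulin genes rose with all 3: Iglv1 by 3.04 ± 0.61 with fTyS, 3.07 ± 0.61 with SEW and 2.48 ± 0.61 with FTY. Jchain, which joins the units of polymeric IgM and IgA, rose by 2.87 ± 0.55, 3.0 ± 0.55 and 2.46 ± 0.55. The plasma cell list of 9 genes averaged 9.43 ± 0.10 in control (n = 4), 10.61 ± 0.17 with fTyS, 10.72 ± 0.14 with SEW and 10.38 ± 0.19 with FTY (n = 3 each). Its shifts were 1.17 ± 0.22 (adjusted p = 0.0187), 1.29 ± 0.22 (adjusted p = 0.00676) and 0.95 ± 0.22 (adjusted p = 0.0286), with adjusted p = 0.682, 0.436 and 0.828 with an estimated correlation. All 3 compounds changed 13 genes alike, and no gene was called in opposite directions. Jchain, Iglv1, Igk, Igkv8-30, Igkv9-120 and Nr4a3 were higher, and Irx3, Mir22hg, Yeats2, Pgpep1, Tmem87a, Zfp763 and B130024G19Rik were lower. The comparisons share the control arrays. Their fold changes correlated across genes at 0.533 to 0.730, against 0.428 to 0.435 in simulations with no effect. When each compound had its own 2 control arrays, so that no array is shared, they correlated at 0.308 to 0.505. Without an effect this correlation is about 0 only on average and for arrays with no other common structure. Skeletal muscle and adipocyte genes varied between these arrays, so that the correlation alone does not show a common effect of the compounds. Skeletal muscle genes averaged 10.27 ± 2.58 with fTyS, 10.15 ± 2.90 with SEW and 6.94 ± 0.22 with FTY, against 7.82 ± 2.38 in control, and adipocyte genes 10.39 ± 1.34, 10.60 ± 1.24 and 10.50 ± 1.44 against 8.82 ± 0.90. The log2 ratio of the 3 prime to the 5 prime control probe sets of Gapdh, a measure of RNA integrity, was 0.219 ± 0.152 in control, 0.0677 ± 0.105 with fTyS, -0.0743 ± 0.123 with SEW and -0.0283 ± 0.0627 with FTY.

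With fTyS against control 23 genes were called, 11 higher and 12 lower, 9 by over 2-fold. The largest increases were in the immunoglobulin genes Igkv5-39 (3.85 ± 0.60), Iglv1, Igkv9-120 (2.92 ± 0.52), Jchain and Igkv8-30 (2.36 ± 0.40). The decreases were largest in B130024G19Rik (-0.90 ± 0.17), the glutamate receptor gene Gria3 (-0.84 ± 0.13), 5031426D15Rik (-0.67), Zfp763 (-0.65) and Zfp40 (-0.53). Of 9 plasma cell genes, 2 were higher over all genes, and 5 higher and 2 lower adjusted over the list alone. The list was no longer called without control replicate 2 (1.15, adjusted p = 0.0879), fTyS replicate 1 (1.08, adjusted p = 0.0559) or fTyS replicate 3 (1.19, adjusted p = 0.0949). Complement genes shifted by 0.36 ± 0.12 (adjusted p = 0.00146; adjusted p = 0.682 with an estimated correlation) and circadian clock genes by -0.23 ± 0.07 (adjusted p = 0.00566; adjusted p = 0.682 with an estimated correlation). Both had 0 genes called over all genes. Adjusted over the list alone, 6 of 12 complement genes were higher, and of 17 clock genes 10 were lower and 3 higher. Interferon response genes had a mean of 0.25 ± 0.18 (adjusted p = 0.0027; adjusted p = 0.682 with an estimated correlation), which was -0.06 without fTyS replicate 3. At an unadjusted p under 0.05 there were 1942 genes. The groups did not overlap for 11% of all genes (chance 5.71%). Quantile normalization gave 14 higher and 17 lower and median centring 8 and 1. The count was 1954 with array weights, 43 with a replicate block, 0 with the Gapdh ratio covariate, 10 with muscle and adipocyte covariates, 51 with these and without control replicate 4, 4 with the muscle covariate and 6 with only the 7 arrays fitted. It was 54, 1 and 68 without control replicates 1, 3 and 4, and 0, 0 and 85 without fTyS replicates 1, 2 and 3. Each of the 10 genes named for its change lost its call without some array, and 8 with both covariates.

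With SEW against control, genes that glucocorticoids induce rose: 7 of 12 were higher over all genes and 9 adjusted over the list alone, among them the chaperone Fkbp5 (1.91 ± 0.40), Map3k6 (1.73), the lipase inhibitor Angptl4 (1.60) and Tsc22d3 (0.74). The list averaged 10.41 ± 0.43 in control and 11.44 ± 0.14 with SEW (n = 4 and 3), a shift of 1.02 ± 0.22 (adjusted p = 8.98e-06; adjusted p = 0.436 with an estimated correlation). Igkv5-39 (3.52 ± 0.60), Ighg3 (2.76 ± 0.76) and Igkv6-14 (2.73 ± 0.44) rose beside Iglv1 and Jchain. Among 9 plasma cell genes, 5 were higher, for example Ighm (2.48), and 1 lower (Sdc1, -0.20), and adjusted over the list alone 6 and 2. The largest decreases were in Prdm8 (-1.87 ± 0.24), the immediate early gene Egr1 (-1.46 ± 0.33), the endothelial gene Esm1 (-1.27 ± 0.20), the DNA demethylase Tet1 (-1.20 ± 0.18) and Serinc5 (-1.19 ± 0.17). S1pr1, the receptor that SEW-2871 targets, rose by 0.80 ± 0.26 (adjusted p = 0.0462), and Sgpp1, an S1P phosphatase, fell by 0.18 ± 0.06 (adjusted p = 0.0381). S1pr1 was no longer called without control replicate 2 or 3 or any of the SEW arrays, and Sgpp1 without control replicate 2, 3 or 4 or SEW replicate 1 or 2. In all, 1889 genes differed, 488 higher and 1401 lower, 43 by over 2-fold, with 595 and 1126 under quantile normalization and 488 and 966 under median centring. No overlap of the groups was seen for 27.6% of all genes (chance 5.71%). The count was 4427 with array weights, 331 with the Gapdh ratio covariate and 746 with only the 7 arrays fitted. It was 1226 and 856 without control replicates 2 and 3 and 592 and 891 without SEW replicates 1 and 3, and 1 of the 10 genes with the largest changes lost its call without some array.

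With FTY against control, the largest decreases were in the clock output gene Dbp (-2.69 ± 0.45), Gm6958 (-1.89 ± 0.42), the clock gene Per3 (-1.59 ± 0.28), Prdm8 (-1.59 ± 0.24) and the matricellular gene Ccn1 (-1.26 ± 0.23). The list of 17 circadian clock genes was not called (-0.28 ± 0.07, adjusted p = 0.0698; adjusted p = 0.828 with an estimated correlation), with 2 genes higher and 6 lower. Opposite changes cancel in this test, so a time-of-day difference stays open. Iglv1, Jchain, Igkv9-120 (2.06) and Igha (1.88) rose, as did the heat shock gene Hspa1a (1.92 ± 0.46). Of 9 plasma cell genes 3 were higher and 1 lower, and adjusted over the list alone 4 and 2. Their list was not called without control replicate 1 (0.92, adjusted p = 0.0669), control replicate 2 (0.93, adjusted p = 0.101) or FTY replicate 3 (0.86, adjusted p = 0.0687). The receptor S1pr3 fell by 0.42 ± 0.10 (adjusted p = 0.0254) and Sgpp1 by 0.22 ± 0.06 (adjusted p = 0.0462), both losing their call without each of at least 5 of the 7 arrays. S1pr3 had -0.40 ± 0.10 with fTyS (adjusted p = 0.0748) and -0.27 ± 0.10 with SEW (adjusted p = 0.0636). T cell and cell cycle genes had means of 0.58 ± 0.31 and 0.47 ± 0.28 (adjusted p = 4.85e-05 and 7.08e-07; adjusted p = 0.828 each with an estimated correlation), and -0.05 each without FTY replicate 3, with Pcna higher (0.45). Glucocorticoid response genes had a mean of 0.54 ± 0.22, with 0 called over all genes and 3 of 12 adjusted over the list alone (adjusted p = 0.00826; adjusted p = 0.828 with an estimated correlation), and 0.40 without FTY replicate 1 (adjusted p = 0.103). FTY changed 353 genes, 62 higher and 291 lower, 19 by over 2-fold. Groups did not overlap for 15.3% of all genes (chance 5.71%). Quantile normalization gave 87 higher and 179 lower, and median centring 50 and 106. The count was 958 with array weights, 0 with the Gapdh ratio covariate, 180 with muscle and adipocyte covariates, 548 with the muscle covariate and without control replicate 4, and 1 with only the 7 arrays fitted. It was 620, 151 and 37 without control replicates 1, 2 and 3, and 96 and 35 without FTY replicates 1 and 3. Of the 10 genes with the largest changes only Dbp and Prdm8 were called without each array in turn.

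Irradiated and unirradiated mice given the same compound were compared to find the radiation response under it. These comparisons share no array with radiation against control. Targets of p53 rose with all 3 compounds: Eda2r by 1.75 ± 0.37 with fTyS and 2.05 ± 0.37 with SEW, and Psrc1 by 1.96 ± 0.43, 2.12 ± 0.43 and, with FTY, 2.27 ± 0.43. The p53 list of 25 genes shifted by 0.49 ± 0.10 with fTyS, with 9 higher over all genes and 15 adjusted over the list alone (adjusted p = 2.54e-13; adjusted p = 0.0481 with an estimated correlation). With SEW it shifted by 0.46 ± 0.10, with 11 higher and 1 lower (adjusted over the list alone 12 and 1; adjusted p = 0.0034; adjusted p = 0.764 with an estimated correlation). With FTY it shifted by 0.47 ± 0.10, with 10 higher and 1 lower (adjusted over the list alone 12 and 1; adjusted p = 0.00266; adjusted p = 0.627 with an estimated correlation), and Ccng1 rose by 0.96 ± 0.20. The 3 comparisons called 22 genes alike. Of these 20 were higher, for example Eda2r, Psrc1, Phlda3, Zmat3, Aen, Polk, Ephx1 and S1pr3, and 2 lower, Fzd4 and Krt79. S1pr3 rose by 0.53 ± 0.10 with fTyS, 0.37 ± 0.10 with SEW and 0.44 ± 0.10 with FTY. Sphk2, a kinase that makes S1P, rose by 0.35 ± 0.09 with SEW and 0.48 ± 0.09 with FTY, while S1pr1 fell by 1.01 ± 0.28 with FTY.

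Under fTyS, radiation changed 59 genes, 43 higher and 16 lower, 7 by over 2-fold, with 1721 at an unadjusted p under 0.05. Groups did not overlap for 15.8% of all genes (chance 10%). Beside Eda2r and Psrc1, the largest increases were in Gm6958 (2.86 ± 0.45), the p53 target Phlda3 (1.16) and the mucin gene Muc4 (1.11 ± 0.17). Tent5c fell by 1.37, Krt79 by 1.28, Galnt15 by 1.0, and the somatostatin receptor gene Sstr4 and the progesterone receptor gene Pgr by 0.83 each. Platelet genes shifted by -0.74 ± 0.21, with 0 called over all genes and 4 of 6 adjusted over the list alone (adjusted p = 8.75e-06; adjusted p = 0.25 with an estimated correlation). Quantile normalization gave 17 higher and 13 lower and median centring 15 and 9. The count was 36 with no filter, 23 with the mean of all probe sets, 3729 with array weights and 142 with a replicate block. It was 29 with the muscle covariate, 157 with it and without control replicate 4, 282 with muscle and adipocyte covariates and without control replicate 4, and 10 with only the 6 arrays fitted. It was 11, 0 and 20 without fTyS replicates 1, 2 and 3 and 10, 100 and 3 without radiation+fTyS replicates 1, 2 and 3. Each of the 10 genes lost its call without some array.

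Under SEW, the largest decreases after radiation were in Igkv5-39 (-3.28 ± 0.65), Igkv6-14 (-3.15 ± 0.47), Igkv8-30 (-2.56), Ighm (-2.38) and Igkv4-68 (-2.32). The plasma cell list shifted by -1.02 ± 0.24 (adjusted p = 0.00563; adjusted p = 0.585 with an estimated correlation), with 4 of 9 genes lower and 1 higher, and 6 and 1 adjusted over the list alone. Radiation raised Gm6958 (2.24 ± 0.45), Psrc1, Eda2r, Agr2 (1.97) and Gp2 (1.87). Of 31 extracellular matrix genes 13 rose, for example the collagen gene Col1a1 (0.89), Mmp14 (0.43) and the protease inhibitor Timp1 (1.22). Adjusted over the list alone, 15 were higher and 1 lower, and the list mean was 0.28 ± 0.09 (adjusted p = 0.00378; adjusted p = 0.8 with an estimated correlation). Of 26 interferon response genes 9 rose and 12 adjusted over the list alone, for example Ifit3 (1.13), with a list mean of 0.46 ± 0.19 (adjusted p = 0.00378; adjusted p = 0.933 with an estimated correlation). Glucocorticoid response genes shifted by -0.90 ± 0.24, with 6 of 12 lower and 8 adjusted over the list alone (adjusted p = 4.29e-05; adjusted p = 0.585 with an estimated correlation). The comparison called 2295 genes, 1788 higher and 507 lower, 75 by over 2-fold. Quantile normalization gave 1527 higher and 588 lower and median centring 1477 and 535. The groups were apart for 42.2% of all genes (chance 10%). The count was 4687 with array weights and 1319 with the Gapdh ratio covariate, and 1236 and 1494 without SEW replicates 1 and 3 and 919 without radiation+SEW replicate 3. Without some array 1 of the 10 genes lost its call.

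Between radiation+FTY and FTY, the largest increases were in the muscle genes Myh2 (4.60 ± 1.41) and Myl2 (3.88), Dbp (2.75 ± 0.48), Gm6958 (2.45) and Psrc1. The largest decreases were in the heat shock genes Hspa1a (-2.40 ± 0.49) and Hspa1b (-1.93), Angptl4 (-1.86), Nr4a3 (-1.67 ± 0.30) and Atp6v1b1 (-1.60). Skeletal muscle genes averaged 10.50 ± 2.79 with radiation+FTY, at 12.14, 7.28 and 12.10 on its 3 arrays, and 6.94 ± 0.22 with FTY. Of 16 monocyte and interstitial macrophage genes 6 rose and 8 adjusted over the list alone, with a mean of 0.44 ± 0.11 (adjusted p = 0.00414; adjusted p = 0.627 with an estimated correlation). Of 10 neutrophil genes 5 rose and 6 adjusted over the list alone, with a mean of 1.11 ± 0.30 (adjusted p = 0.01; adjusted p = 0.627 with an estimated correlation), and 0.83 without radiation+FTY replicate 3 (adjusted p = 0.0595). Of 14 oxidative stress defence genes 3 rose, Srxn1 (0.65, but -0.02 by 1 of its 3 other probe sets), Gsr (0.58) and Gsta2 (1.20), and 7 adjusted over the list alone, with a mean of 0.42 ± 0.09 (adjusted p = 0.00781; adjusted p = 0.627 with an estimated correlation). The comparison called 1826 genes, 1181 higher and 645 lower, 79 by over 2-fold. It gave 945 higher and 720 lower with quantile normalization and 906 and 640 with median centring. No overlap was seen for 31.8% of all genes (chance 10%). The count was 605 with only the 6 arrays fitted, 1128 and 932 without FTY replicates 1 and 2, and 961 and 1043 without radiation+FTY replicates 1 and 2. Without some array 3 of the 10 genes lost their call.

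The interaction of radiation and compound tested whether the radiation response differed with the compound. The neutrophil term was negative for each. It was -2.05 ± 0.41 with fTyS, with 4 of 10 called and 8 adjusted over the list alone (adjusted p = 2.28e-09). It was -1.42 ± 0.41 with SEW, with 3 called and 4 adjusted over the list alone (adjusted p = 0.00021), and -0.90 ± 0.41 with FTY, with 1 called and 3 adjusted over the list alone (adjusted p = 0.004). With an estimated correlation the adjusted p was 0.0969, 0.589 and 0.917. The term of S1pr3 was positive with each, at 0.61 ± 0.14, 0.45 ± 0.14 and 0.53 ± 0.14 (adjusted p = 0.0388, 0.0388 and 0.0328). With fTyS the largest negative terms were those of Stfa2l1 (-3.34 ± 0.68), Igkv9-120 (-3.09), Clec4e (-2.82 ± 0.53), Clec4d (-2.69 ± 0.48) and Wfdc17 (-2.51 ± 0.43). The largest positive terms were those of A330076H08Rik (1.51), Itih4 (1.30), Pacc1 (1.25, but negative by both of its other probe sets), B130024G19Rik (1.23) and Gm33248 (1.15). With SEW they were negative in Igkv5-39 (-3.73 ± 0.88), Iglv1 (-3.42), Jchain (-3.34), Igkv9-120 (-3.27) and Igkv6-14 (-3.08). They were positive in Agr2 (2.80), Gp2 (2.30), Prdm8 (2.25 ± 0.36), Calcb (1.99) and A330076H08Rik (1.84). With FTY they were negative in Hspa1a (-3.50 ± 0.67), Hspa1b (-2.90), Nr4a3 (-2.83 ± 0.41), Nfil3 (-2.50) and Igha (-2.31). Positive ones were those of Dbp (3.51 ± 0.66), Prdm8 (2.11), Per3 (1.78), Gsta2 (1.72) and Hlf (1.56). The list of circadian clock genes was not called with FTY (0.31 ± 0.10, adjusted p = 0.538), with 6 of 17 genes positive and 1 negative. Glucocorticoid response genes had a term of -1.13 ± 0.33 with SEW, with 5 of 12 called over all genes and adjusted over the list alone (adjusted p = 0.00021; adjusted p = 0.589 with an estimated correlation). Their list shifted by 0.23 ± 0.22 with radiation alone (not called) and by -0.90 ± 0.24 under SEW.

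The interaction called 175 genes with fTyS (128 positive, 47 negative), 1797 with SEW (1356 and 441) and 885 with FTY (617 and 268). All 3 share the radiation and control arrays and are not independent. Of the 10 genes named for their terms, 8 lost their call without some array with fTyS, 3 with SEW and 4 with FTY, and 5, 0 and 1 lost it under quantile normalization. The balance of directions depended on the scaling. With quantile normalization it was 45 positive and 49 negative for fTyS, 954 and 642 for SEW, and 358 and 407 for FTY. With median centring it was 16 and 29, 790 and 635, and 268 and 403. For fTyS the count was 2076 with array weights, 365 with muscle and adipocyte covariates, 449 with these and without control replicate 4, 263 with the muscle covariate and without control replicate 4 and 3 with only the 13 arrays fitted. It was 85 and 58 without control replicates 2 and 3, and 92, 34 and 114 without fTyS replicates 1, 2 and 3. It was 103 and 31 without radiation replicates 1 and 2, and 72 and 37 without radiation+fTyS replicates 1 and 3. For SEW it was 3366 with array weights, 575 with the Gapdh ratio covariate, 1126 without SEW replicate 1, 1140 without radiation replicate 1 and 888 without radiation+SEW replicate 3. For FTY it was 1741 with array weights, 449 with the Gapdh ratio covariate, 522 with the mean of all probe sets and 375 with only the 13 arrays fitted. It was 496 without control replicate 3, 542 and 544 without FTY replicates 1 and 2, 582 and 504 without radiation replicates 1 and 3, and 552 and 441 without radiation+FTY replicates 1 and 2.

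The compounds, all at 0.1 mg/kg, were compared with each other. Without radiation, limma called 0 genes between fTyS and FTY, which share a backbone and differ in the phosphonate group, with 769 at an unadjusted p under 0.05 and 827 with array weights. The closest gene was the phospholipase family gene Pld4, with 0.70 ± 0.11 (adjusted p = 0.0698), which did not pass. As lists 11 were called, with 0 members called over all genes or adjusted over the list alone. Complement genes were higher with fTyS by 0.29 ± 0.12 (adjusted p = 7.74e-05), interferon response genes by 0.35 ± 0.19 (adjusted p = 9.21e-06), but 0.04 without fTyS replicate 3 (adjusted p = 0.486), and skeletal muscle genes by 3.34 ± 1.87 (adjusted p = 9.7e-06). The adjusted p of these 3 lists was 0.816 with an estimated correlation. Limma also called 0 genes between FTY and SEW, with 1178 at an unadjusted p under 0.05 and 809 with array weights. Gria3, Dpy19l3 and Meis2 came closest and did not pass (adjusted p = 0.257). Here 12 lists were called, also without a member called over all genes. Glucocorticoid response genes were lower with FTY by -0.48 ± 0.24 (adjusted p = 0.000158; adjusted p = 0.461 with an estimated correlation). Circadian clock genes were lower by -0.21 ± 0.07 (adjusted p = 0.00333; adjusted p = 0.461 with an estimated correlation), with 1 of 17 higher and 4 lower adjusted over the list alone. Ciliated cell genes were higher by 0.19 ± 0.11 and skeletal muscle genes lower by -3.21 ± 1.87 (adjusted p = 2.76e-05 and 1e-05; adjusted p = 0.612 each with an estimated correlation). The median half-width of the 95% interval of these differences was 0.222, so that smaller differences could be missed. Between fTyS and SEW 200 genes were called, 165 higher and 35 lower with fTyS, 14 by over 2-fold. The groups did not overlap for 25.6% of all genes (chance 10%). Glucocorticoid-induced genes were lower with fTyS than with SEW, with Fkbp5 at -1.98 ± 0.43 (adjusted p = 0.0248), Zbtb16 at -1.83 and Map3k6 at -1.71, next to Fam107a (-1.76) and Klhl29 (-1.07). Of 12 such genes 3 were lower, over all genes and adjusted over the list alone (list mean -0.72 ± 0.24; adjusted p = 1.69e-05; adjusted p = 0.66 with an estimated correlation). Adgre4 (1.22 ± 0.21), Map2k6 (1.16), the cold-induced gene Cirbp (1.08), the antigen transporter gene Tap1 (1.07) and Cttnbp2 (1.05) were higher with fTyS. The count was 75 with quantile normalization, 119 with median centring, 67 with the mean of all probe sets, 4478 with array weights and 115 with the Gapdh ratio covariate. It was 561 with muscle and adipocyte covariates, 640 with these and 322 with the muscle covariate without control replicate 4, and 19 with only the 6 arrays fitted. It was 22, 83 and 303 without fTyS replicates 1, 2 and 3 and 3, 79 and 30 without SEW replicates 1, 2 and 3. Each of the 10 genes lost its call without some array.

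With radiation, 511 genes differed between radiation+fTyS and radiation+FTY, 238 higher and 273 lower with fTyS, 4 by over 2-fold. Groups did not overlap for 21.6% of all genes (chance 10%). Immediate early and heat shock genes were higher with fTyS by 0.51 ± 0.14 (adjusted p = 1.62e-07; adjusted p = 0.394 with an estimated correlation). Of these 19 genes, 4 were called over all genes and 9 adjusted over the list alone. Thbs1 (1.16 ± 0.25), the anion exchanger gene Slc26a4 (0.97), Megf11 (0.85), Thoc2l (0.79 ± 0.11) and Angptl1 (0.70) were higher with fTyS. Myh7 (-2.69 ± 0.61), Ankrd63 (-1.39), Upk3b (-1.05), Bnc1 (-0.98) and Wt1 (-0.97) were lower. Sphk2 was lower by -0.38 ± 0.09 and Asah1 higher by 0.24 ± 0.06. Neutrophil genes were lower with fTyS by -0.80 ± 0.30, with 0 called over all genes and 2 adjusted over the list alone (adjusted p = 0.0266; adjusted p = 0.559 with an estimated correlation). This call was lost without radiation+fTyS replicate 2 (-0.93, adjusted p = 0.0635), radiation+fTyS replicate 3 (-0.68, adjusted p = 0.0763) or radiation+FTY replicate 3 (-0.52, adjusted p = 0.222). Quantile normalization gave 204 higher and 375 lower and median centring 134 and 231. The count was 329 with no filter, 2500 with array weights and 0 with only the 6 arrays fitted. It was 6, 932 and 198 without radiation+fTyS replicates 1, 2 and 3 and 17 and 48 without radiation+FTY replicates 1 and 2, and 9 of the 10 genes lost their call in this way.

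Limma called 0 genes between radiation+fTyS and radiation+SEW, with 1414 at an unadjusted p under 0.05, 1101 with array weights and 4 without radiation+fTyS replicate 2. The closest was Zfp53, with 0.44 ± 0.07 (adjusted p = 0.0526), which did not pass. B cell genes were higher as a list with fTyS by 0.77 ± 0.33 (adjusted p = 1.44e-10; adjusted p = 0.621 with an estimated correlation), with 0 of 15 called over all genes or adjusted over the list alone. Between radiation+FTY and radiation+SEW limma also called 0 genes, with 1036 at an unadjusted p under 0.05, 4 with array weights, 23 with muscle and adipocyte covariates and without control replicate 4, and 4 without radiation+FTY replicate 2. Scgb3a2, a secretoglobin of airway cells, had -0.16 (adjusted p = 0.166) and did not pass. As lists, extracellular matrix genes were lower with FTY by -0.26 ± 0.09 (adjusted p = 7.81e-11; adjusted p = 0.176 with an estimated correlation), with 10 of 31 lower adjusted over the list alone. Neutrophil genes were higher by 0.86 ± 0.30 (adjusted p = 6.51e-05; adjusted p = 0.199 with an estimated correlation), with 6 of 10 higher adjusted over the list alone. In both lists 0 genes were called over all genes.

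Genes of S1P handling were followed throughout, since the compounds act on S1P receptors. Of 11 such genes fixed in advance 10 were measured above the filter. Neither the list of S1P receptors and carriers (6 genes tested) nor that of sphingolipid metabolism (35 genes tested) was called in any of the 19 comparisons. The smallest adjusted p was 0.217 for the former, and 0.0544 for the latter with radiation+FTY against radiation (mean -0.06 ± 0.04; adjusted p = 0.67 with an estimated correlation). With radiation against control S1pr1 had 0.16 (adjusted p = 0.84) and the kinase Sphk1 0.02 (adjusted p = 0.98).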

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

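Tests of other splits of the arrays were chosen before their results were seen. All tests of explanations for the 3 patterns below and the counts over splits that part same-number pairs were chosen only after.

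The array labelled control replicate 4 stood apart from the other control arrays in p53 target genes (mean 10.15, others 9.56 to 9.71 among unirradiated arrays) and in its position between unirradiated and irradiated arrays, which was 1.002 on a scale where the compounds alone average near 0 and radiation with a compound near 1. A candidate explanation is an irradiated lung under a control label: over the 14 genes of this scale outside the p53 list its position was 0.978, inside the range of the 12 irradiated arrays (0.603 to 1.143) and outside that of the other control arrays (0.206 to 0.452), with radiation alone, whose arrays did not choose these genes, at 0.603 to 0.782. A swap of labels within the series needs an irradiated array placed among the unirradiated ones, and the lowest irradiated position over all 22 genes was 0.670, above the 0.316 of the highest other unirradiated array, which argues against it. The log2 Gapdh ratio of the array, 0.0988, lay within the range of the others (-0.170 to 0.429), which argues against RNA quality. Its neutrophil mean, 8.12, lay below those of radiation alone (9.39 to 10.15) and within the range of radiation with a compound (7.64 to 9.57), so that a wrong label stays open, as does damage to the animal by another route, which was not tested.

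Skeletal muscle genes differed between arrays of the same group, from 6.34 to 12.51 as a list mean, with Acta1 between 7.02 and 13.35. Neighbouring tissue taken with the lung is a candidate source: of the values of 5 muscle genes outside the list, 95.6% lay above their median on the 9 arrays with a mean over 10. On 7 of these 9 arrays squamous epithelium genes, listed after the values were seen, averaged over 9, and Krt4 ranged from 5.87 to 12.66. An effect of the treatment would keep arrays of a group together, but 7 of the 8 groups spanned more than 2 log2 units, which argues against it. No biological explanation beyond the treatment was tested.

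Neutrophil genes were higher with radiation alone and lower with each compound added. With the muscle and adipocyte means as covariates the shift with radiation was 1.017 times that without, which argues against carried-over tissue. Red blood cell genes shifted by -0.111 times the neutrophil shift with radiation, which argues against more blood with radiation alone than in control. The decrease with each compound was not tested in this way. With radiation alone red blood cell genes averaged 8.35 to 8.84 and platelet genes 8.58 to 8.74. With fTyS, SEW and FTY added, the former averaged 7.92 to 8.18, 7.80 to 8.94 and 8.50 to 9.33. The latter averaged 7.87 to 8.25, 7.88 to 8.39 and 8.38 to 8.96. Less blood with fTyS or SEW added therefore stays open. The interaction was negative with 3 of 3 compounds. This largely restates the pattern, the 3 share the radiation arrays, and none was called with an estimated correlation. A radiation response lowered by each compound therefore stays open. So do a collection batch of the radiation group and infection or stress of its animals, which were not tested.

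A control array was taken to stand apart where its gap to the nearest other was a larger part of the range of the 4 arrays than the critical value of Dixon's test at 95%. By this rule a fibroblast mean of 10.71 on control replicate 1 was below the others (10.77 to 10.79), a skeletal muscle mean of 11.38 on control replicate 2 was above them (6.40 to 6.76), and a Stfa2l1 level of 7.23 on control replicate 4 was above them. With the 2 values of control replicate 4 given first, 5 of 74 quantities tested stood apart, where chance gives 3.7.

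The radiation response differed with the compound for 175 genes with fTyS, 1797 with SEW and 885 with FTY. Of 100 splits of the arrays, only the real one reached the count with each compound, and the highest others gave 173, 857 and 692. For SEW the lowest count without a single array also lay above the highest other split, so that chance is an unlikely source. For FTY the lowest such count lay below the highest other split. For fTyS the margin of 2 genes was smaller than the spread of the count without single arrays (31 to 229). Chance is therefore not excluded for fTyS and FTY either. With fTyS, where the same-number pairs correlated, 1 of the 64 splits that part the 3 pairs on both sides reached the count (175; highest other 173). Such differences were also called for gene lists. With fTyS they were 0.641 for B cells, 0.422 for NK and cytotoxic cells, 0.173 for alveolar type 2 cells, 0.271 for cholesterol and fatty acid synthesis, 0.355 for the circadian clock, 0.279 for fibroblasts, -0.521 for the glucocorticoid response, -0.346 for monocytes and interstitial macrophages, -2.05 for neutrophils, 0.167 for p53 targets (0.0332 without control replicate 4, where the call was lost with an adjusted p of 0.463) and -0.919 for platelets. With SEW they were 0.381 for cholesterol and fatty acid synthesis, 0.378 for ciliated cells, -0.333 for cytokines, -1.13 for the glucocorticoid response, -1.42 for neutrophils, -1.38 for plasma cells and -0.642 for platelets. With FTY they were -0.589 for T cells and -0.449 for the cell cycle, but 0.0390 and 0.0763 without FTY replicate 3. They were 0.838 for B cells, 0.429 for cholesterol and fatty acid synthesis, -0.210 for endothelial cells and -0.817 for the glucocorticoid response. They were -0.535 for immediate early and heat shock genes, -0.900 for neutrophils and 4.03 for skeletal muscle. Without some array 6 of 11 list calls were lost with fTyS, 4 of 7 with SEW and 5 of 9 with FTY. None of these list calls held with an estimated correlation, where the smallest adjusted p was 0.0969. Single genes of S1P handling with such a difference were S1pr3 (0.611 with fTyS, 0.453 with SEW, 0.525 with FTY) and Sgpp1 (0.279 with SEW, but -0.117 by 1 of its 2 other probe sets).

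The other comparisons gave these counts over splits of the arrays. Against control, 2 of 35 splits reached the count for radiation (569, highest other 757), fTyS (23, 34) and FTY (353, 433). Chance cannot be excluded by this test for these comparisons. For SEW 1 of 35 splits reached the count (1889, highest other 1492). That is the smallest share that 35 splits allow and was not adjusted over the comparisons. Chance is thus less likely for SEW but not excluded. The split with 757 genes moved the array labelled control replicate 4 to the radiation side, and those with 34 and 433 moved control replicate 1 to the side of the compound. Comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05. Of these, 1 split reached the real count for radiation+fTyS, radiation+SEW and radiation+FTY against radiation (111, 321 and 391; highest other 0 each), radiation+SEW against SEW (2295; 0), radiation+FTY against FTY (1826; 8), fTyS against SEW (200; 0) and radiation+fTyS against radiation+FTY (511; 392). For radiation+fTyS against fTyS 2 did (59; highest other 1259), and the split with 1259 set fTyS replicate 3 and radiation+fTyS replicates 1 and 3 against fTyS replicates 1 and 2 and radiation+fTyS replicate 2, which points to a structure of the arrays other than the treatment. The adipocyte means, compared after this split was seen, were 8.87, 7.74 and 8.37 on the first side and 11.42, 10.87 and 11.77 on the second. Where the real count was 0, all 10 splits reached it, with highest others of 1 (fTyS against FTY), 0 (FTY against SEW), 1 (radiation+fTyS against radiation+SEW) and 3 (radiation+FTY against radiation+SEW). Where all 3 same-number pairs of arrays correlated, the real split was also set against the splits that part 3 pairs. For radiation against control 2 of 8 reached the count (569; highest other 757), and for fTyS against control 1 of 8 did (23; 19). Of 4 such splits, 1 reached it for radiation+fTyS against fTyS (59; 0) and against radiation (111; 0), and 4 for FTY against SEW (0; 0). Splits as few as 8 or 4 are too few for a share under 0.05, and the split with 1259 genes parted fewer pairs.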

How the results depend on the processing

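The covariates, and list tests and scores without an array, were chosen after the results were seen. The cause of the shifts below was not tested, except that a fit of only the arrays compared has fewer arrays to estimate the spread, that no filter tests more genes, that leaving out an array leaves fewer arrays, and that the replicate block takes up control replicate 4 by itself. No called named gene changed sign under the settings run on it, while the means of called lists changed sign 14 times and many calls were lost. Of 388 calls of named genes, 59 were lost with quantile normalization, 76 with median centring, 97 with the Gapdh covariate, 77 with the muscle covariate, 72 with muscle and adipocyte covariates, 221 with only the arrays compared, and 1 with array weights; leaving out an array ended 1064 and kept 1876. Of 192 list calls, an estimated correlation ended 188, quantile normalization 19 and a replicate block 15; the muscle covariate ended 30 and kept 153, and both covariates ended 43 and kept 133. A list used as a covariate has no value under it. Genes called under neither setting were not compared in sign, and a pseudocount of 1 moved no count by over 1.5 times. Genes near the 40th percentile of signal are limited by background, whose correction is not stated.

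Counts of genes moved by over 1.5 times as follows. Array weights gave 1138 for radiation, 1954 for fTyS, 4427 for SEW and 958 for FTY against control; 1220, 1444 and 1249 for fTyS, SEW and FTY with radiation against radiation; 3729 for radiation+fTyS against fTyS and 4687 for radiation+SEW against SEW; 827 for fTyS against FTY, 4478 for fTyS against SEW, 809 for FTY against SEW, 2500 for radiation+fTyS against radiation+FTY, 1101 against radiation+SEW, and 4 for radiation+FTY against radiation+SEW; and 2076, 3366 and 1741 for the interactions with fTyS, SEW and FTY. A replicate block gave 867 for radiation, 43 for fTyS and 142 for radiation+fTyS against fTyS. Only the arrays compared gave 60 for radiation, 6, 746 and 1 for fTyS, SEW and FTY against control, 0, 102 and 6 for these with radiation against radiation, 10 for radiation+fTyS against fTyS, 605 for radiation+FTY against FTY, 19 for fTyS against SEW, 0 for radiation+fTyS against radiation+FTY, and 3 and 375 for the interactions with fTyS and FTY. The Gapdh covariate gave 0, 331 and 0 for fTyS, SEW and FTY against control, 1319 for radiation+SEW against SEW, 115 for fTyS against SEW, and 575 and 449 for the interactions with SEW and FTY. Median centring gave 9 for fTyS, 156 for FTY, 24 for radiation+fTyS against fTyS, 119 for fTyS against SEW and 45 for the interaction with fTyS; quantile normalization gave 30, 75 and 94 for the last 3. The mean of all probe sets gave 184 for radiation+FTY against radiation, 23 for radiation+fTyS against fTyS, 67 for fTyS against SEW and 522 for the interaction with FTY. No filter gave 36 for radiation+fTyS against fTyS, 329 for radiation+fTyS against radiation+FTY and 1 for radiation+FTY against radiation+SEW. For radiation+fTyS against radiation+SEW a pseudocount of 64, a filter at the 60th percentile and eBayes without trend each gave 1.

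Muscle and adipocyte covariates gave 10 for fTyS, 180 for FTY, 208 and 101 for fTyS and FTY with radiation against radiation, 561 for fTyS against SEW, 2 for radiation+fTyS and 4 for radiation+FTY against radiation+SEW, and 365 for the interaction with fTyS. Without control replicate 4 they gave 1185 for radiation, 51 for fTyS, 254 and 129 for fTyS and FTY with radiation against radiation, 282 for radiation+fTyS against fTyS, 640 for fTyS against SEW, 3 and 23 for radiation+fTyS and radiation+FTY against radiation+SEW, and 449 for the interaction with fTyS. The muscle covariate gave 4 for fTyS, 90 for radiation+FTY against radiation, 29 for radiation+fTyS against fTyS and 2 for radiation+fTyS against radiation+SEW. Without control replicate 4 it gave 960 for radiation, 548 for FTY, 108 for radiation+FTY against radiation, 157 for radiation+fTyS against fTyS, 322 for fTyS against SEW, 3 and 2 for radiation+fTyS and radiation+FTY against radiation+SEW, and 263 for the interaction with fTyS.

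Leaving out each array gave 232 to 884 for radiation, 0 to 85 for fTyS, 592 to 2183 for SEW and 35 to 620 for FTY against control. It gave 18 to 173, 49 to 257 and 38 to 472 for fTyS, SEW and FTY with radiation against radiation, and 0 to 100, 919 to 1978 and 932 to 1532 against the compound. Between compounds the ranges were 0 to 0 for fTyS against FTY, 3 to 303 for fTyS against SEW, 0 to 0 for FTY against SEW, 6 to 932 for radiation+fTyS against radiation+FTY, and 0 to 4 for radiation+fTyS and for radiation+FTY against radiation+SEW. The interactions ranged from 31 to 229, 888 to 2093 and 441 to 1165. Of the list tests without an array, 1090 kept the call, 276 lost it and 9 reversed in both mean and test. Interferon genes with fTyS against control ranged from -0.0582 without fTyS replicate 3 to 0.455 without fTyS replicate 2. The other 8 reversed without FTY replicate 3 and were farthest on the other side without FTY replicate 1. Cell cycle genes ranged from -0.0512 to 0.740 for FTY against control, 0.270 to -0.521 for radiation+FTY against FTY, 0.384 to -0.407 for fTyS against FTY, -0.161 to 0.631 for FTY against SEW and 0.0763 to -0.715 in the interaction. The list of T cells ranged from 0.116 to -0.873 for radiation+FTY against FTY, 0.309 to -0.680 for fTyS against FTY and -0.0771 to 0.912 for FTY against SEW. The mean alone changed sign, with the call lost, for T cells without FTY replicate 3 (FTY against control, -0.0514, and the interaction, 0.0390) and for club and secretory cells without radiation+FTY replicate 3 (radiation+FTY against radiation, 0.0445). The same held for cardiac muscle for FTY against control with muscle and adipocyte covariates (-0.0753, and -0.105 without control replicate 4).

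The radiation score with 50 genes in each direction was -1.36, -1.51 and -0.851 for fTyS, SEW and FTY with radiation against radiation, and 0.269, 0.397 and 0.949 against the compound alone. The cross-fitted score was 0.361 for SEW with radiation against radiation, the reverse direction. It was near 0 for fTyS (0.00886) and FTY (-0.0140), with signs that depend on single arrays. It reversed to -0.152, -0.422 and -0.342 for the compounds against control, less so without control replicate 4. It was 1.20 and 1.37 for radiation+SEW and radiation+FTY against the compound. Slopes over all genes were 0.0733 for SEW and 0.0919 for FTY. The slopes over the radiation genes, without each array, stayed within 0.153 to 0.210 for fTyS, 0.215 to 0.278 for SEW and 0.433 to 0.566 for FTY.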

Other observations

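The values below were picked only after they were seen and were not tested. Genes induced by glucocorticoids varied between single arrays as well as with SEW. Fkbp5 stood at 10.30 to 10.56 with SEW and 9.10 to 9.74 with FTY. It stood at 9.75 on control replicate 1 and at 10.63 on radiation replicate 1. Zbtb16, a transcription factor of the same list, stood at 12.35 to 12.37 with SEW, 12.34 on control replicate 1 and 12.04 on radiation replicate 1.

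Dbp, a gene whose level follows the time of day, stood at 7.76 to 9.02 with FTY and at 10.16 to 11.70 in control; the time of collection is not given. T cell genes averaged 9.50 on FTY replicate 3 and at most 8.10 on the other 24 arrays, and cell cycle genes averaged 9.31 on the same array. Thymocyte genes averaged 10.96 on it and at most 8.98 on the other 24. Whether thymus was taken with this lung was not tested, and the T cell and cell cycle results with FTY cannot be told apart from it. Interferon response genes averaged 9.99 on fTyS replicate 3. Cdkn1a stood at 9.72 and 9.80 on control replicates 3 and 2, and at 11.34 and 12.02 on control replicates 1 and 4. Eda2r stood at 8.89 on control replicate 4, at 6.59 to 7.54 on the other unirradiated arrays, and at 8.43 to 9.04 on the irradiated arrays. The first 3 principal components held 43.9%, 11.3% and 7.97% of the variance over the genes tested.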
